A study of Homo sapiens with 38 samples.

How the data were processed

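RNA was extracted from sections of fixed, embedded tissue and made into stranded total RNA libraries with a low-input kit, per the labels' protocols. The authors deposited 1 table of TPM values for 18952 gene symbols in 38 specimens, and each column summed to 1000000. Salmon and the GRCh38 build are named in the submitters' processing notes, without a version. The annotation and the choice of listed genes are not given in the sources used here. Because TPM keeps no depth, the precision that depth sets is unknown, and a rise of abundant transcripts lowers the values of all others. Fixed, embedded tissue yields fragmented RNA, which can lower detection of some transcripts.

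Treatment groups came from the labels and patients from the titles, which tie each specimen to 1 of 12 patients. Patients are numbered 1 to 12 here in the order of the titles. The design fixed before the data were examined expected either counts or normalized values, and the branch for normalized values was used, so count models were not fitted. XIST, TSIX and genes found only on the Y chromosome (45 in all) were left out. A check of labels by Y-linked genes, given only as a count, found 2 post-treatment specimens that did not match the other specimens of their patient; they were kept in the main tests and left out in an alternative. By correlation over genes, 24 of 38 specimens were closest to a specimen of the same patient and 14 to one of another patient, which was not taken as a mismatch. No 2 specimens held identical values.

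Genes with at least 1 TPM in at least 12 of 38 specimens were tested, 15030 in all. Values were log2(TPM + 1), and specimens of 1 patient at 1 time were averaged, which gave 12 pre-treatment and 12 post-treatment values. limma 3.58.1 in R 4.3.3 was fitted with the patient as a block, with trend and robust variance, and p-values were adjusted by Benjamini-Hochberg. The pairing comes from the titles, since both values of a pair are from the same patient. The correlation of paired deviations from the group means ranged from 0.037 to 0.778 with a median of 0.317, and was above 0.1 in 10 of 12 patients.

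The 21 gene lists and 16 marker lists were fixed before the data were examined, and 665 of 676 list genes were matched to the table, older symbols included. Lists were tested with camera at a preset correlation of 0.01, adjusted over 37 lists, and with an estimated correlation, fry and an exact sign-flip over 4096 sign patterns as alternatives. Distances were tested by permutation with 100000 resamples or by exact enumeration, as 4 comparisons without adjustment across them. Named genes were the 12 largest rises and 12 largest falls past the threshold with a mean of at least 2 TPM that moved the same way in at least 10 of 12 patients, the 3 members of smallest adjusted p in each list described, and CDKN1A, MDM2, MKI67, TOP2A, CD274, CD8A, COL1A1 and VEGFA. The results of 2 genes that this rule names are not reported here.

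The limma step was tested on simulated data for the 12 against 12 comparison with 15030 genes. Of these, 200 were changed by 1 or 2 log2 units and a list of 20 more was shifted by 0.7. The step recovered 55% of genes changed by 1 log2 unit and 97% of those changed by 2, and 3.1% of its calls were unchanged genes. Simulated noise was independent between genes, whereas real list genes were correlated (up to 0.91, for skeletal muscle), so these shares may differ in the real data. The distance tests were tested on 3000 simulated genes, where the comparison of spread between patients failed when all specimens were averaged. Other alternatives were quantile normalization, other filters, pseudocounts of 0.1 and 0.5, other units of replication, covariates and leaving out each patient. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for the rest, and gene positions came from GENCODE release 29 on GRCh38.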

Results

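Bulk RNA was sequenced from formalin-fixed, paraffin-embedded soft tissue sarcoma specimens of 12 patients, taken before or after chemoradiation, which combines cytotoxic drugs with ionising radiation. The series title names undifferentiated pleomorphic sarcoma, a malignant tumour of mesenchymal cells without a specific line of differentiation. There were 13 pre-treatment specimens (11 patients gave 1 and 1 patient gave 2) and 25 post-treatment specimens (1 patient gave 1, 9 patients gave 2 and 2 patients gave 3). The deposited values were TPM, a length-normalised measure of transcript abundance, for 18952 gene symbols, and each specimen summed to 1000000, so the sequencing depth is unknown and no counting interval was given. Genes above 0 numbered 14841 to 16884 in pre-treatment and 15168 to 18015 in post-treatment specimens. The patient was the replicate, and all changes are on the log2(TPM + 1) scale, which understates changes of low genes.

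The first comparison asked which genes differed between tumours before and after chemoradiation. Immediate early genes, which are transcribed within minutes of a stimulus, showed the largest rises. FOSB, a subunit of the AP-1 transcription factor, rose by 4.34 ± 0.60 (log2, SE, n = 12 patients, limma adjusted p = 0.0162), from a geometric mean of 4.19 to 104.4 TPM, and was higher in 12 of 12 patients. FOS, its relative, rose by 3.30 ± 0.55 (limma adjusted p = 0.0179, 11 of 12 patients). C7, a complement component made by fibroblasts, rose by 3.09 ± 0.48 in 12 of 12 patients, and APOD, an apolipoprotein, by 2.88 ± 0.52 in 11 of 12. Other genes among the 12 with the largest rises were DUSP1 (2.70), CYR61 (2.67), CTGF (2.57), EGR1 (2.39), SNCG (2.38) and BHLHE41 (2.29), with limma adjusted p between 0.0162 and 0.0333.

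Falls were smaller. BRIP1, a helicase of the Fanconi pathway, fell by 1.64 ± 0.33 (log2, SE, n = 12, limma adjusted p = 0.0316), from a geometric mean of 18.97 to 5.42 TPM, and was lower in 11 of 12 patients. SMC1B, a meiotic cohesin subunit, fell by 1.62, and CBX2, a Polycomb protein, by 1.46. The homeobox genes HOXA6 and HOXA9 fell by 1.502 and 1.23. CCNB1, the cyclin that drives entry into mitosis, fell by 1.38 ± 0.32 in 10 of 12 patients (limma adjusted p = 0.0459). The remaining genes with the largest falls were HIST2H3D (-1.42), CMTM1 (-1.34), MTBP (-1.30), EXOSC4 (-1.15), RCCD1 (-1.09) and KRTAP5-11 (-1.07). HIST2H3D and KRTAP5-11 belong to multigene families whose reads can be shared between copies, so their values are uncertain.

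**Figure D1:**
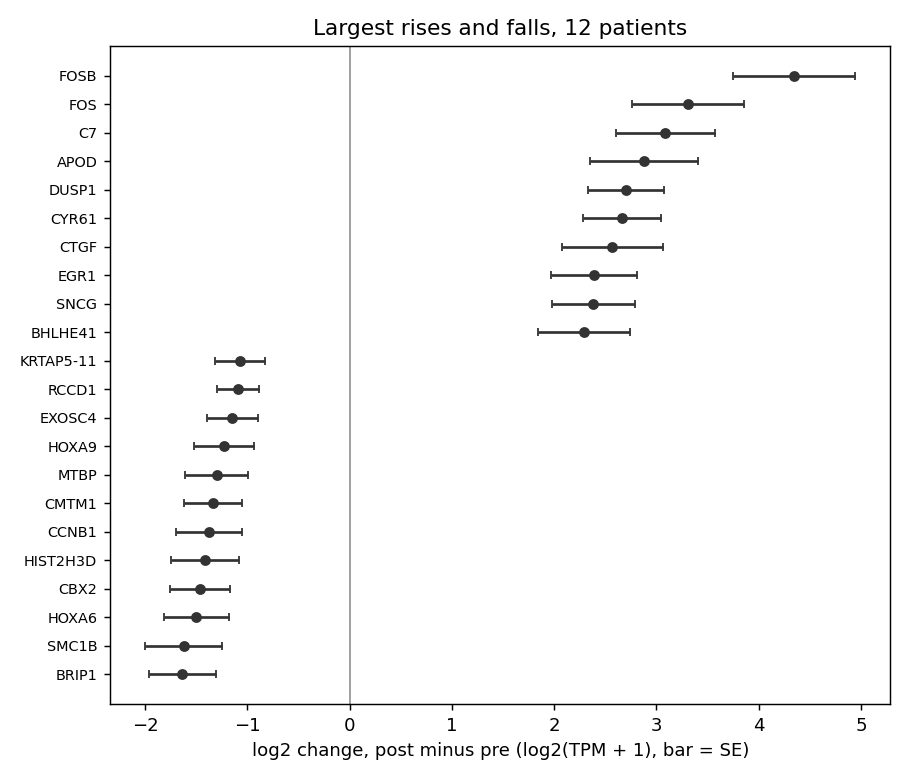
Log2 change, post minus pre, on the x axis for 10 of the 12 genes with the largest rise and the 12 with the largest fall, 1 gene per line, as the fitted change (point) and its SE (bar) over 12 patients. FOSB stands highest at 4.34 and BRIP1 lowest at -1.64.

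Of 15030 genes tested with limma and the patient as a block, 234 passed an adjusted p of 0.05, 169 higher and 65 lower after treatment, and 3803 had an unadjusted p under 0.05. The median change of all genes was -0.0482. The count changed with single patients and with the fit: it ranged from 30 to 1448 when 1 patient at a time was left out (30 without patient 9, 1448 without patient 2, and a move of over 1.5 times for every patient but number 6), was 21 without the patient block, and was 0 with skeletal muscle marker level as a covariate (1631 at unadjusted p under 0.05) and 0 without 4 patients whose pre-treatment specimens were alike (1709 at unadjusted p under 0.05). All 234 genes kept their direction in both of the last fits, which is no separate support because they were picked in these same specimens. The balance of rises and falls also changed, from 700 higher and 748 lower without patient 2 to 28 and 2 without patient 9. With the muscle covariate the change was 3.80 for FOSB (4.34 without it), 2.53 for FOS (3.30), 3.01 for C7 (3.09), 2.23 for DUSP1 (2.70), 1.07 for NFKBIA (1.17) and -1.09 for CCNB1 (-1.38). Without the 4 patients these were 3.95, 2.67, 2.79, 1.98, 0.97 and -1.44 in the same order.

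Signs of tissue composition and RNA content were compared as well. Skeletal muscle markers differed by 2.17 ± 3.93 (mean log2 change, SD over 12 patients) and were higher in 10 of 12 patients. They ranged from -5.50 to 8.17 and did not pass an exact sign-flip permutation (adjusted p = 0.121). The mitochondrial share of TPM averaged 4.78% ± 2.27 before and 7.89% ± 3.57 after (SD, n = 12 patients, exact sign-flip permutation p = 0.041, two-sided, higher in 9 of 12). Genes at 1 TPM or more averaged 14019 ± 316 before and 14480 ± 474 after (exact sign-flip permutation p = 0.000977, higher in 11 of 12). Genes above 0 did not differ clearly (exact sign-flip permutation p = 0.258, higher in 6 of 12). Nor did the share of TPM in the 10 highest genes (exact sign-flip permutation p = 0.103, higher in 9 of 12).

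Among the 37 gene and marker lists, the immediate early genes had the largest shift outside skeletal muscle. Their mean change was 1.88 ± 1.25 (SD over patients), above 0 in 12 of 12 patients; 11 of 19 members rose and 0 fell, and 19 rose adjusted over the list alone. The list passed camera with a preset correlation (adjusted p = 1.69e-20) but not with an estimated correlation (adjusted p = 0.164). It passed an exact sign-flip permutation over patients (adjusted p = 0.00903). NF-kB and inflammatory cytokine genes differed by 0.85 ± 0.45, again above 0 in 12 of 12 patients, and 4 of 20 rose (11 adjusted over the list alone; adjusted p = 0.114 with an estimated correlation). They included NFKBIA, the inhibitor that NF-kB induces (1.17 ± 0.16 SE, limma adjusted p = 0.0162), and the neutrophil chemokines CXCL3 (1.67) and CXCL2 (1.63). Muscle markers, the mitochondrial share and these lists were all higher after treatment.

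The lists of p53 targets and senescence-associated genes were higher after treatment. For p53 targets the mean change was 0.59 ± 0.56 (SD, 10 of 12 patients), 1 of 26 rose over all genes and 13 adjusted over the list alone (adjusted p = 0.218 with an estimated correlation, 0.0294 by sign-flip permutation). BTG2, an antiproliferative p53 target, rose by 1.05 ± 0.19 (SE, limma adjusted p = 0.0207) and is also a member of the immediate early list. GDF15 at 1.42 ± 0.35 and CDKN1A, which encodes the cell cycle inhibitor p21, at 1.396 ± 0.35 narrowly missed the threshold (limma adjusted p = 0.0506 and 0.0552), and MDM2 stood at 0.69 ± 0.19 (0.0612). Senescence-associated genes differed by 0.85 ± 0.80, with 2 of 18 past the threshold and 6 adjusted over the list alone (adjusted p = 0.218 with an estimated correlation, 0.0294 by sign-flip permutation). TIMP1, a metalloproteinase inhibitor, was 1 of these (1.34 ± 0.29 SE, limma adjusted p = 0.041). PAPPA stood at 1.502 (0.0587). In the 4 patients with alike pre-treatment specimens the p53 list changed by 0.74 to 1.44 and the senescence list by 1.32 to 1.97. In the other 8 patients the ranges were -0.39 to 0.96 and -0.62 to 1.21. Among apoptosis regulators TNFRSF10A (1.25) and MCL1 (0.95) rose, and MCL1 is also a member of the immediate early list. The list of 22 apoptosis regulators did not pass camera (mean 0.14 ± 0.25, adjusted p = 0.232, and 0.509 with an estimated correlation).

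Proliferation lists were lower after treatment in most patients. G2/M and mitosis genes differed by -1.06 ± 1.47 (SD) and were lower in 8 of 12 patients; CCNB1 alone fell over all genes, and 21 of 27 fell adjusted over the list alone. The list passed camera with a preset correlation (adjusted p = 7.2e-10), and neither with an estimated correlation (adjusted p = 0.293) nor by sign-flip permutation (adjusted p = 0.0576). MKI67 was at -1.02 ± 0.40 (SE, limma adjusted p = 0.134), TOP2A at -1.36 ± 0.44 (0.0908) and BUB1 at -1.37 ± 0.38 (0.0668). G1/S and DNA replication genes differed by -0.72 ± 0.97 (9 of 12 patients lower), 0 of 27 fell over all genes and 14 adjusted over the list alone (adjusted p = 0.293 with an estimated correlation, 0.0572 by sign-flip permutation). The lead members were MCM4 (-0.90), MCM7 (-0.69) and MCM5 (-0.70), subunits of the replicative helicase. Homologous recombination and Fanconi genes differed by -0.69 ± 0.93, with 1 of 19, BRIP1, past the threshold and 12 adjusted over the list alone (adjusted p = 0.293 with an estimated correlation). End joining and damage sensing genes differed by -0.27 ± 0.24, lower in 10 of 12 patients (adjusted p = 0.222 with an estimated correlation, 0.0294 by sign-flip permutation), with no member of 18 past the threshold and TP53BP1 at -0.42. Replication-dependent histones did not pass (mean -0.39 ± 1.28, camera adjusted p = 0.05, 0.636 with an estimated correlation), and their mean was -0.20 without patient 7.

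**Figure D2:**
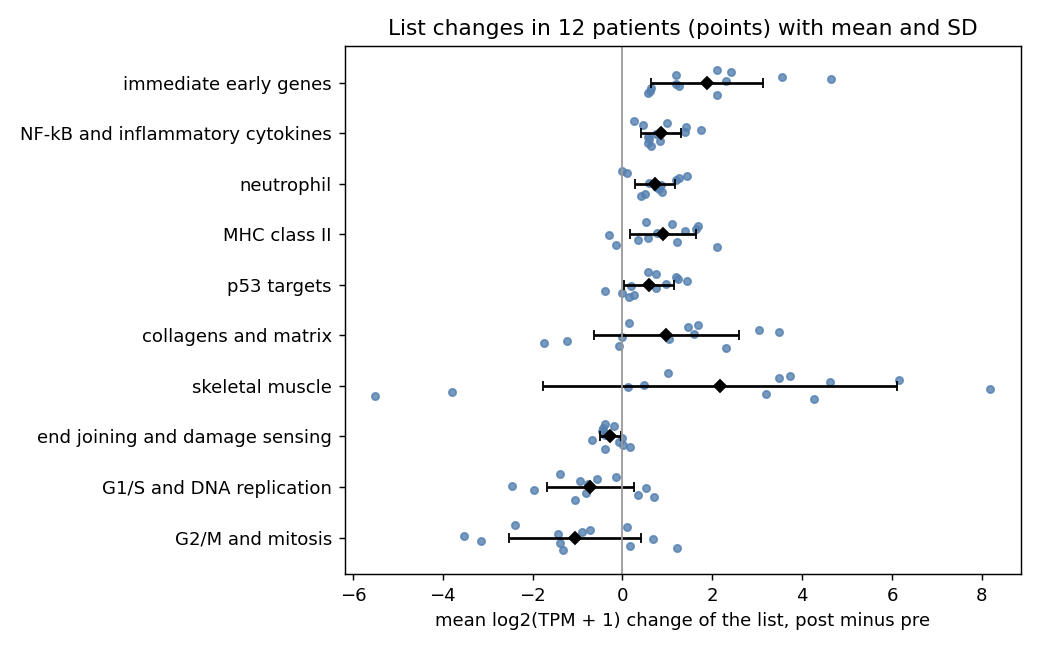
Mean log2(TPM + 1) change, post minus pre, on the x axis for 10 lists, with 1 point per patient (n = 12) and the mean with its SD as a diamond and bar. Immediate early genes lie above 0 in 12 of 12 patients, and G2/M genes below 0 in 8.

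Immune markers were on average higher after treatment, though not in every patient. MHC class II genes, which present antigen to CD4 T cells, differed by 0.90 ± 0.74 (SD, 10 of 12 patients), with 3 of 11 past the threshold and 11 adjusted over the list alone (adjusted p = 0.218 with an estimated correlation, 0.0181 by sign-flip permutation). HLA-DQA1 rose by 1.06 ± 0.23 (SE, limma adjusted p = 0.04), HLA-DPB1 by 1.01 and CTSS by 0.87. Macrophage markers differed by 0.89 ± 0.91 (8 of 12 patients, adjusted p = 0.218 with an estimated correlation). Of 18, 3 rose, the scavenger receptors CD163 (1.11) and MARCO (2.17) and the complement receptor VSIG4 (1.09). In the 4 patients with alike pre-treatment specimens macrophage markers changed by 0.99 to 2.23 and MHC class II genes by 1.09 to 1.68. In the other 8 patients the ranges were -0.24 to 1.94 and -0.30 to 2.10. The 4 patients with lower macrophage markers were all among these 8. Neutrophil markers differed by 0.73 ± 0.44 in 11 of 12 patients (adjusted p = 0.114 with an estimated correlation, 0.00903 by sign-flip permutation), and CSF3R (1.25) and S100A8 (1.86) rose. T cell markers differed by 0.55 ± 0.61, and IL7R alone of 13 rose (1.19 ± 0.27 SE, limma adjusted p = 0.0452; list adjusted p = 0.218 with an estimated correlation). Dendritic cell markers differed by 0.71 ± 0.69 with 0 of 10 past the threshold (adjusted p = 0.218 with an estimated correlation), and cytotoxic lymphocyte markers by 0.48 ± 0.63 with 0 of 13 (0.292). Interferon gamma and MHC class I genes differed by 0.38 ± 0.82 with 0 of 22 past the threshold (camera adjusted p = 0.000238, 0.38 with an estimated correlation). CD8A stood at 0.47 ± 0.31 and CD274, which encodes PD-L1, at 0.45 ± 0.32 (SE, limma adjusted p = 0.354 and 0.389).

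Smaller or more variable immune lists followed. Plasma cell markers differed by 0.62 ± 1.004 (SD; camera adjusted p = 0.0257, 0.317 with an estimated correlation) and mast cell markers by 0.52 ± 1.47 (0.0213, and 0.421 with an estimated correlation). The mast cell mean was 0.31 without patient 1 and 0.34 without patient 12. B cell markers, of which 4 of 12 were tested, differed by 0.18 ± 1.29 (0.474, and 0.688 with an estimated correlation), and their mean ranged from 0.03 without patient 3 to 0.45 without patient 2, with 0.06 without patient 7, 0.11 without patient 4 and 0.34 without patient 11. Immune checkpoint genes differed by 0.12 ± 0.38 (0.247, and 0.509 with an estimated correlation), and by 0.05 without patient 3. The type I interferon list had a mean change of 0.0013 ± 0.98, a median of -0.0128 and a camera direction upward (adjusted p = 0.812, 0.951 with an estimated correlation), so its signs differed. Without the 4 patients with alike pre-treatment specimens its direction turned downward and it passed (camera adjusted p = 0.000774, against 0.0913 to 0.996 over its other alternatives).

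Stromal and other tissue markers were on average higher as well, with wide spread between patients. Normal fibroblast markers differed by 1.35 ± 1.68 (SD), and C7 alone of 12 rose (adjusted p = 0.256 with an estimated correlation). Collagens and matrix genes differed by 0.98 ± 1.61 with 0 of 28 past the threshold (camera adjusted p = 1.34e-05, 0.379 with an estimated correlation), and COL1A1 stood at 1.37 ± 0.77 (SE, limma adjusted p = 0.272). For TGF-beta targets the mean change was 0.87 ± 1.001, and 3 of 19 rose (adjusted p = 0.256 with an estimated correlation, 0.0346 by sign-flip permutation). Among those that rose were CTGF and CYR61, and CYR61 is also a member of the immediate early list. The fibroblast, collagen and TGF-beta lists leaned on the 4 patients with alike pre-treatment specimens. In them fibroblast markers changed by 1.93 to 4.21, collagens by 1.47 to 3.49 and TGF-beta targets by 1.06 to 2.65. In the other 8 patients the ranges were -1.21 to 3.19, -1.74 to 2.31 and -0.97 to 1.04. Adipocyte markers differed by 0.98 ± 1.404, and LEP, the hormone leptin, rose by 1.52 (adjusted p = 0.235 for the list with an estimated correlation). Pericyte and smooth muscle markers differed by 1.07 ± 1.64 (0.293 with an estimated correlation), endothelial markers by 0.63 ± 0.80 (0.257), Schwann cell and nerve markers by 0.84 ± 0.68 (0.218), erythroid markers by 1.32 ± 1.44 (0.218), and epithelium and skin markers by 0.74 ± 1.89 (0.381), with no member past the threshold in these 5 lists. The epithelium and skin mean rested on patient 9 and was 0.20 without that patient. No skeletal muscle marker of 18 passed either (camera adjusted p = 8.04e-07, 0.317 with an estimated correlation), and TNNC1 led at 2.89 ± 0.72 (SE, limma adjusted p = 0.0552). By sign-flip permutation over patients, TGF-beta targets, Schwann cell and nerve markers (adjusted p = 0.00903) and erythroid markers (0.0346) passed. Fibroblast (0.0516), collagen (0.0947), adipocyte (0.0657), pericyte (0.0809), endothelial (0.0572), epithelium (0.0576) and skeletal muscle lists (0.121) did not pass that permutation.

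Metabolic and stress lists moved little. Hypoxia and glycolysis genes differed by 0.21 ± 0.62 (SD; camera adjusted p = 0.0672, 0.532 with an estimated correlation), or 0.14 without patient 9, and VEGFA, the vascular growth factor, stood at -0.64 ± 0.29 (SE, limma adjusted p = 0.179). Nuclear oxidative phosphorylation genes differed by -0.0705 ± 0.18 (0.279, and 0.541 with an estimated correlation), or -0.11 without patient 10. Heat shock and unfolded protein genes differed by 0.19 ± 0.45 (0.0213, and 0.383 with an estimated correlation), and HERPUD1 rose by 0.67. Cytosolic ribosomal protein genes differed by -0.21 ± 0.59 (0.00863, and 0.568 with an estimated correlation). The ribosomal mean was -0.13 without patient 8 and -0.12 without patient 9. The heat shock and ribosomal lists changed sign without the 4 patients with alike pre-treatment specimens. Sarcoma-associated genes had a mean change of 0.14 ± 0.21 and a median of -0.0992, so the signs differed (0.428, and 0.532 with an estimated correlation). In all, 29 of 37 lists passed camera with a preset correlation, 24 higher and 5 lower, 0 passed with an estimated correlation (adjusted p 0.114 to 0.951), 14 passed fry and 13 passed the sign-flip permutation.

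The next comparisons asked how alike specimens of 1 tumour were, as 1 minus Pearson's r over the 2000 most variable genes. Post-treatment specimens of the same patient lay closer (0.195 ± 0.12, SD, 15 pairs) than those of different patients (0.445 ± 0.14, 285 pairs; one-sided permutation p = 1e-05, the smallest the resamples can give). Pre- and post-treatment profiles of the same patient lay closer (0.331 ± 0.16) than those of different patients (0.524 ± 0.16; one-sided permutation p = 1e-05, again the smallest possible), and in 6 of 12 patients the own post-treatment profile was the nearest. Within 11 patients, pre- to post-treatment distances (0.390 ± 0.14) exceeded distances between post-treatment specimens (0.206 ± 0.13) in 10 (exact sign-flip permutation p = 0.00781, two-sided). Without the 4 patients with alike pre-treatment specimens that difference was 0.137 (exact permutation p = 0.0781, n = 7). Only 1 patient gave 2 pre-treatment specimens, so distances between pre-treatment specimens of a patient could not be set beside these. The difference therefore cannot be credited to treatment rather than to time or procedure.

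**Figure D3:**
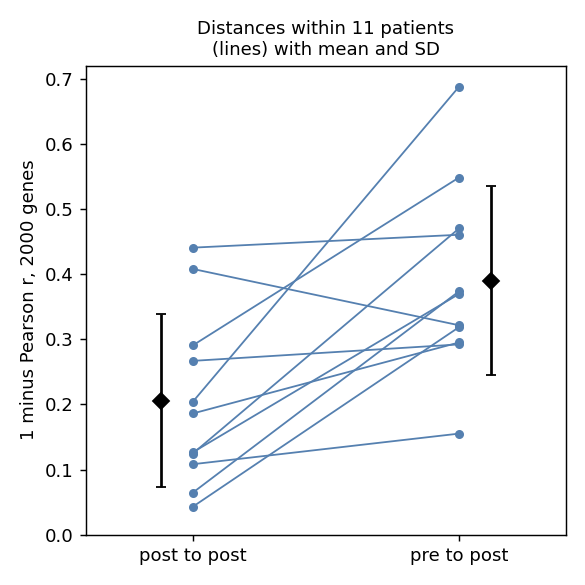
Distance (1 minus Pearson r over 2000 genes) on the y axis between post-treatment specimens and between pre- and post-treatment specimens of the same patient, 1 line per patient (n = 11), with the mean and SD as diamonds and bars. The means are 0.206 and 0.390, and 10 of 11 lines rise.

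Tumours of different patients lay closer to each other after treatment on average, but whether this passed the test changed with the patients included. With 1 specimen per patient and time, the mean distance between patients was 0.447 after and 0.573 before, a difference of -0.125 (exact permutation p = 0.0176, two-sided, n = 12). Without the 4 patients with alike pre-treatment specimens it was -0.0678 and did not pass (exact permutation p = 0.273, n = 8). The comparison fixed in advance averaged all specimens of a patient and gave 0.385 and 0.564, a difference of -0.179 (exact permutation p = 0.0137), but averaging more post-treatment specimens lowers that distance by itself: 20 of 20 simulated sets with no effect of time passed it, against 1 of 20 with 1 specimen per patient and time. Its p-value is therefore not evidence of a change.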

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

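Fits with mitochondrial genes removed, with mitochondrial share or muscle markers as covariates, and without mismatching specimens or alike patients (also with 1 specimen per patient and time), and the sign-flip test of lists, were chosen after seeing the data. Of 15030 genes, 234 passed with the patient as a block; the count was 21 with no replicate block, 2847 with all 38 specimens and the block, 2584 with the patient as a random effect, 55 with 1 specimen per patient and time, 90 without a filter, 146 with the stricter filter, 37 with the number of detected genes as a covariate, 12 with the mitochondrial share, 0 with the muscle marker level (limma, 1631 at unadjusted p under 0.05) and 0 without the 4 alike patients (limma, 1709). The block fit on all 38 specimens treats specimens of 1 tumour as replicates, while the random-effect fit allows a correlation of 0.355 among specimens of a patient. The stricter filter tested 10629 genes. Causes of the changes in count were not tested. Leaving out 1 patient gave 30 to 1448 genes. Rises made up 72.2% of called genes in the main fit. That share ran from 44.7% with the patient as a random effect to 100% with the mitochondrial share as a covariate. Counts stayed within 1.5 times under quantile normalization (258), pseudocounts of 0.1 (184) and 0.5 (233), averaging on the TPM scale (306), without mitochondrial genes (328) and without the mismatching specimens (258). All 234 genes kept their direction wherever tested, and 150 of 150 under the stricter filter. Since they were picked in these same specimens, a kept direction was nearly fixed in advance.

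Lists past the threshold numbered 29 with camera, 0 with an estimated correlation (adjusted p 0.114 to 0.951), 14 with fry and 13 by sign-flip. The block changed no count of lists (29 without it). Without the 4 alike patients, 3 lists turned direction: type I interferon (adjusted p = 0.000774), heat shock (0.698) and cytosolic ribosomal proteins (0.00254); the cause was not tested. Apart from these, list results under settings other than leaving out a patient held their side of the threshold in 292 cases, lost it in 68 and gained it in 6. Named genes did so in 1650, 244 and 148 cases. Among the distances, 2 no longer passed without the alike patients, where 8 and 7 patients remained. These were the spread between patients (-0.0806, and -0.0678 with 1 specimen per patient and time) and the excess of pre- to post-treatment over post- to post-treatment distance (0.137). All other distance results kept their call. DESeq2 and voom need counts and were not run, nor was upper-quartile normalization, which was planned for counts only. Depth is unknown, so its limit on low genes cannot be given.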

Other observations

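All tests in this part except those of glucocorticoid-responsive genes and of genes private to a tumour were chosen after the result was seen.

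Glucocorticoid-responsive genes were higher after treatment. The rises of TSC22D3 (2.21 ± 0.37, log2, SE, n = 12, limma adjusted p = 0.0179), PER1 (1.81) and DUSP1 (2.70), genes that glucocorticoid receptors induce, prompted a list of 11 further such genes, written before their values were seen. Their mean change was 1.08 ± 0.80 (SD over 12 patients), above 0 in 11 of 12 (exact sign-flip permutation p = 0.00146). FKBP5, a chaperone of the receptor, rose by 1.98 ± 0.40 (SE, limma adjusted p = 0.0348) and CEBPD by 0.89 (0.0462), so 2 of the 11 passed. Those that did not ranged from MT1X (1.95) to CDKN1C (0.50, adjusted p = 0.355) and MT1E (0.18, adjusted p = 0.611). Exposure to glucocorticoids around surgery or therapy may account for part of the rise, as a hypothesis: the labels used here give no medication, several of these genes also respond to other stimuli, and muscle markers moved the same way.

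The 234 genes past the threshold were set against 100 draws of splits that swap pre and post within patients, the real one included. As many genes were called in 2 of 100, a share under 0.05, and the highest other split called 238 with 1 patient swapped. The swaps treat patients as independent, which is not settled for the 4 patients with alike pre-treatment specimens. Without those 4 patients, 0 genes passed. The splits therefore do not settle whether chance can be excluded for the count of genes. For lists with camera, 5 of 100 splits passed as many as the real 29, the highest other 32, so chance cannot be excluded for the count of lists.

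The rise of immediate early genes is a pattern to follow up. Against skeletal muscle as its whole cause, the list's expected change at no change in muscle markers was 1.54 ± 0.38 (SE, 12 patients), against 1.88 unadjusted, and in the 2 patients whose muscle markers were lower after treatment the list stood at 0.57 and 0.63, above 0 but among the lowest of the 12, which leaves room for a part played by muscle. With the muscle covariate the FOSB change was 3.80 ± 0.63 in place of 4.34 ± 0.60, and its call ended (adjusted p 0.0162 before, 0.121 after) as the estimate fell slightly and no gene of 15030 passed. Handling, such as time to fixation or a different kind of procedure at the 2 times, stays open: the list was higher in 12 patients, and it cannot be told apart from treatment because the labels used here give no procedure. A response of the tissue to chemoradiation stays open too.

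For the lower mitosis genes, a rise of mitochondrial transcripts within the fixed TPM total was argued against, since the list's mean change was -1.02 ± 1.48 (SD) without mitochondrial genes and -1.06 with them. Dilution of tumour cells by other tissue cannot be told apart from lower proliferation. The 4 patients with alike pre-treatment specimens were not considered here, and the 2 specimens that did not match their patient were left out. Of the other 8 patients, 5 had at least 10 genes private to their tumour. In these 5 the mitosis list changed by 0.08 ± 0.52 (SE) relative to those genes, against a change of -0.50 in the same patients and specimens. The condition that 2 SE be smaller than that change, which was not met, was added after this value was seen. Lower proliferation after chemoradiation remains possible and was not tested separately.

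Pre-treatment specimens of 4 patients (8 to 11, consecutive in the order of the titles) resembled each other. They were picked by CD36 above 1000 TPM, so its separation restates the choice. CD36, a fatty acid receptor on chromosome 7 (80369575 to 80679277, GRCh38), was at 6340 to 7720 TPM in them and at 2.84 to 138 in the other 8 patients. GNAT3, a taste-associated G protein gene that overlaps CD36 in position (80458671 to 80512020), was at 250 TPM or more in the same 4 and at 0.354 or less in the others, and overlapping genes can share reads. After treatment the same 4 patients again had the highest values, CD36 at 801 to 3860 TPM against at most 380 and GNAT3 at 5.36 to 39.6 against at most 2.26. Of 77 pairs of pre-treatment specimens of different patients, 7 correlated as highly as specimens of 1 patient do (0.83 ± 0.09, SD, minus 1 SD, over 14 pairs without the 2 specimens that did not match), 5 of them among these 4 patients. With all 16 pairs (0.80 ± 0.12) these counts were 12 and 6. The 4 patients gave 1 pre-treatment specimen each and so form only 6 pairs, nearly all or all of which reached that correlation. Specimens of 1 tumour under several labels may be a cause. The post-treatment values of CD36 and GNAT3 go with the labels, and wrong labels on pre-treatment specimens alone would not give them. Over all tested genes, paired deviations from the group means correlated at 0.037 to 0.316 in the 4 and 0.195 to 0.778 in the other 8. Pre- to post-treatment distances were 0.374 to 0.688 in the 4. They were 0.155 to 0.470 in the others with at least 2 post-treatment specimens. The labels are therefore not settled. A shared tumour type stays open and was not tested. A gain of the region cannot be told apart: 2 of 4 tested genes within 1 Mb (GNAT3 and GNAI1) had the same 4 patients highest, MAGI2 and SEMA3C did not, and 455 of all tested genes (3.03%) did.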
